A study of Mus musculus with 8 samples.

How the data were processed

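Kidneys of p53 null and p53 wild-type mouse embryos were compared on 8 arrays with 2 colours, at embryonic day 15.5 and on a C57BL/6 background per the labels. Each array carried null RNA labelled with one dye and wild-type RNA labelled with the other. Replicate 1 had 4 arrays, in 2 dye-swapped pairs, and replicates 2 and 3 had 2 dye-swapped arrays each. The labels call the 3 replicates biological. How many embryos or litters went into each RNA is not given in the sources used here. The file headers place replicate 1 on slide 1 (scan 1) and replicates 2 and 3 on slide 2 (scan 2).

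Total RNA was isolated on silica columns and labelled by direct incorporation of dye into cDNA, per the labels' protocols. The scanner files deposited by the authors hold spot and background brightness as linear intensity, with flags per spot, extracted with Agilent Feature Extraction 10.5.1.1 per the file headers; the submitters' processing notes name version 6.1. The same files hold the program's log ratio, which is the log10 of red over green, per the file headers. The deposited value table holds 8 columns in log10. Each column equalled the program's log ratio after the sign was turned to null over wild type (correlation 1 on each array, largest difference 4.94e-06), so scale, centring and direction of the table are settled. Its column medians were 0.0083, −0.0024, 0.0042 and 0.0015 for the arrays of replicate 1, 0.00083 and 0.0064 for replicate 2, and 0.0064 and 0.011 for replicate 3. The table leaves between 7732 and 14364 of 43379 spots of an array empty, and the rule behind the empty cells is not given in the sources used here.

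Ratios were computed from the median spot signal and median local background, since the files used here hold no mean spot signal although a mean had been planned. Background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3. The 1639 control spots had weight 0 in the loess and were then left out, spots flagged as outliers were set to missing, and saturated spots were kept, of which there were 0. Spots of one probe were averaged; 245 probes were spotted 10 times. Every array was turned to log2 null over wild type. The mean of each dye orientation was taken first and the 2 orientations were then averaged within a replicate, which cancels a dye effect. Of 41174 probes, 20880 were kept because one genotype was well above background on at least 50% of the arrays of each replicate, and 20865 had a value in all 3 replicates and were tested. An offset of 50 compresses ratios of dim probes.

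The files used here hold no gene name column. Probes were named through their RefSeq accession, without versions, in a table of the GRCm38.p6 annotation; 25097 of 41174 probes were named, and 4257 of the tested probes stayed unnamed and were counted but not named. The file headers give mm9 as the build of the array design, so no coordinates are printed, and the annotation served only for names, chromosomes and neighbourhood. A gene is represented by its kept probe with the highest mean intensity. This gave 12000 genes; of the 3777 with more than 1 tested probe, 957 had probes that differed in sign.

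The test was limma's moderated fit of the 3 replicate values against 0 (two-sided, 4.22 degrees of freedom in all), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A permutation of signs over 3 replicates cannot go below p = 0.25. Gene lists were tested with camera (preset correlation 0.01, adjusted over the 26 lists with at least 5 measured members), and again with a correlation estimated for each list and with fry. With an estimated correlation camera has only the residual degrees of freedom of 3 values, so a call over 26 lists was hardly possible. For stroma, with an estimated correlation of −0.018, the camera p still rose from 2.3e-05 to 0.042. A high adjusted p from that test thus does not by itself show correlated genes. The 30 lists cover p53 target genes, kidney cell types, other cell types a dissection may bring, the cell cycle, apoptosis, metabolism, hypoxia, stress, imprinted and sex-linked genes. They, the tests, the rule for named genes and the alternatives were set before the data were examined, except where said otherwise. The rule took Trp53, then 12 genes per direction past the threshold and of the same sign in all 3 replicates and both dyes, or by the smallest unadjusted p with such signs where too few passed, and then up to 4 genes of each list with the smallest p. Some genes picked by this rule are not reported here and were not replaced; they stayed in all tests and list values.

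The fit was tested on simulated data with 20865 probes at their measured spread, of which 200 were changed. Of 50 probes each, 1 was recovered at 1.5-fold, 23 at 2-fold, 49 at 4-fold and 48 at 8-fold, with 4 false calls among 20665 unchanged probes. For the list tests, on 12000 genes, a list shifted by −0.50 (log2) was recovered with 0 other lists called. The simulated probes varied independently of each other and without a slide difference. In the data the estimated correlation was 0.86 for the glycolysis list and 0.99 for the hypoxia list. The simulation thus checks the calculation, and not the power or the false calls of the fit and list tests under such a structure.

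Signal over background limits which probes can be tested. The median spot over its local background was 1.66 to 1.74 in red and 2.10 to 2.44 in green on slide 1, and 1.23 to 1.36 and 1.47 to 1.71 on slide 2. Between 57.8% and 62.8% of probes were well above background on the arrays of slide 1, and between 46.9% and 51.4% on slide 2. For levels per genotype, channels were separated after loess and Aquantile scaling. Where a genotype was not well above background on any array of a replicate and the other was on all of them, a bound is given for that replicate as "at least N-fold": the brighter genotype's mean log2 level against the mean of, per array, the higher of the lowest level among probes well above background and the dim probe's own.

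Alternatives were no background correction, an offset of 16, the Feature Extraction log ratio, median centring, Aquantile scaling, 2 other filters, the value table, leaving out each replicate, the first pair of replicate 1 alone, all 8 arrays with the replicate as a random effect with and without a dye term, slide as a fixed block, 1 value per slide, no replicate block, a trended robust prior, weights by arrays, an unadjusted threshold with a fold of 1.5, probes averaged per gene, and other list tests. The wild-type RNA of replicates 2 and 3 counted as 1 sample, lists without shared genes, and lists of retinoic acid pathway and circadian clock genes were added after seeing the data.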

Results

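Gene expression in kidneys of p53 null mouse embryos was set against that of wild-type embryos at day 15.5 of gestation, a stage at which nephrons are still being induced at the edge of the organ. Each of the 8 arrays compared null with wild-type RNA directly. They formed 3 biological replicates, with 4 arrays for replicate 1 and 2 arrays each for replicates 2 and 3, and 4 arrays carried the null RNA in Cy5. Values are log2 ratios of null over wild type, given as mean ± SD over the replicates (n = 3) unless said otherwise.

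The comparison asked which transcripts differ when p53 is lost from the developing kidney. The targeted gene Trp53 had a ratio of −0.67 ± 0.36 (0.629 of the wild-type level) on its brighter probe, which was spotted 10 times. The ratio was −1.08, −0.47 and −0.45 in replicates 1, 2 and 3 and negative on all 8 arrays. It did not pass the threshold over all probes (limma, adjusted p = 0.279). A second Trp53 probe had 0.16 ± 0.13 (adjusted p = 0.387). The deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing. Without replicate 1 the brighter probe passed (−0.46, adjusted p = 1.5e-06), as it did with slide as a fixed block (−0.77, adjusted p = 2.4e-11), where the spread comes from replicates 2 and 3 of 1 slide alone. The same contrast on 1 value per slide did not pass (adjusted p = 0.9998).

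**Figure D1:**
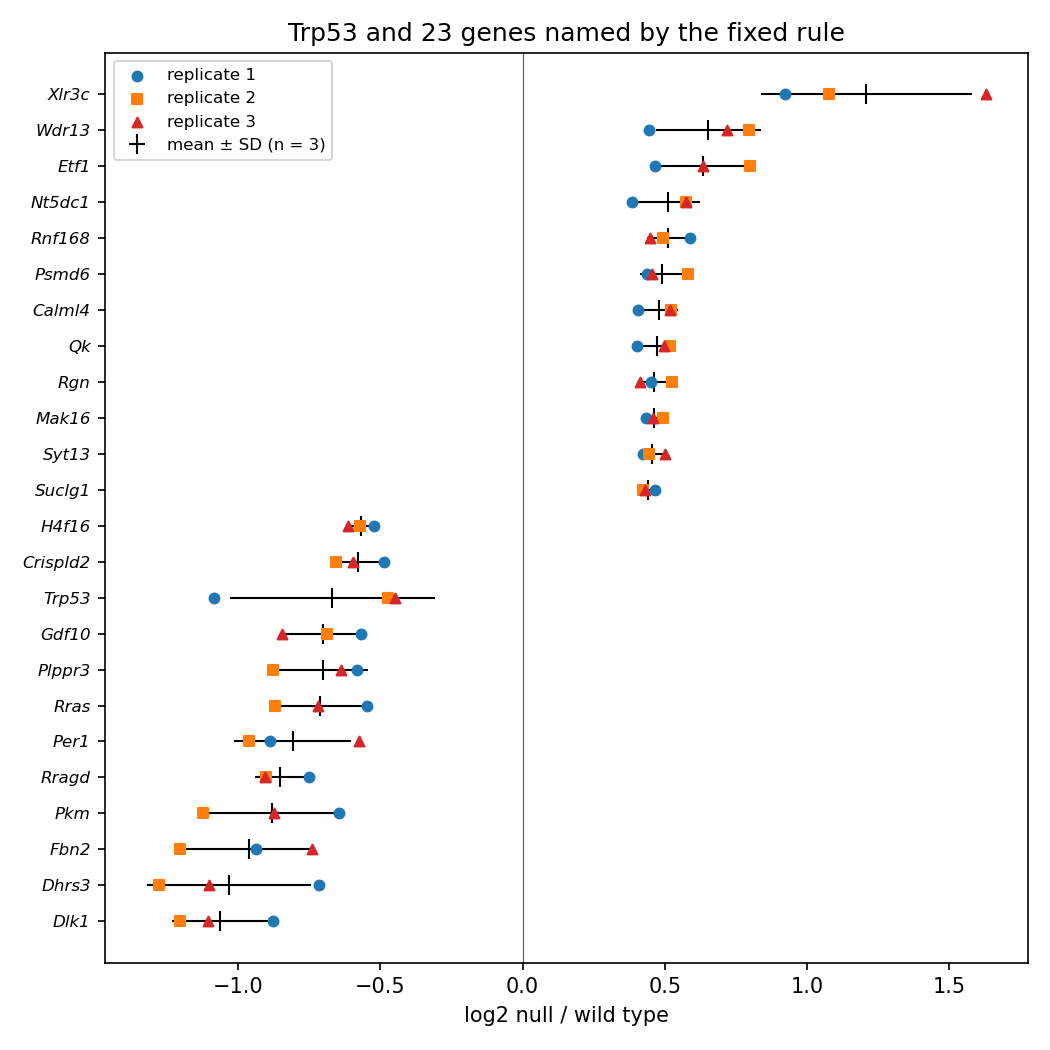
Log2 null over wild-type ratios (x axis) of Trp53 and 23 genes named by the fixed rule; symbols are the 3 replicates, and the tick with its bar is the mean ± SD (n = 3). Trp53 sits at −1.08 in replicate 1 and at −0.47 and −0.45 in replicates 2 and 3; none of these genes passed the threshold.

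Among genes with 1 sign over all replicates and both dyes, those with the smallest p in limma's test included Dlk1, an imprinted membrane protein of the Notch ligand family, at −1.06 ± 0.17, and Rragd, a GTPase that signals amino acid supply to mTORC1, at −0.85 ± 0.09. Also lower in each replicate were Dhrs3, a retinaldehyde reductase (−1.03 ± 0.29), Fbn2, a microfibril protein (−0.96 ± 0.23), the glycolytic enzyme gene Pkm (−0.88 ± 0.24), the clock gene Per1 (−0.81 ± 0.20) and Gdf10, a ligand of the TGF-beta family (−0.70 ± 0.14). Rras, Plppr3, Crispld2 and H4f16 had −0.71, −0.70, −0.58 and −0.57. Of the genes named by this rule with higher values in null, the X-linked gene Xlr3c had 1.21 ± 0.37. Wdr13 had 0.65 ± 0.18, the translation termination factor gene Etf1 0.63 ± 0.17, and Nt5dc1 0.51 ± 0.11. The ubiquitin ligase gene Rnf168, which acts in the DNA damage response, had 0.51 ± 0.07. The proteasome subunit gene Psmd6, Calml4, the RNA-binding protein gene Qk, Rgn, Mak16, Syt13 and Suclg1 lay between 0.44 and 0.49. Second probes of Wdr13 and Nt5dc1 gave 0.02 and 0.11, while second probes of Dhrs3, Etf1 and Mak16 gave −0.89, 0.41 and 0.41.

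None of these genes passed the threshold (limma, adjusted p = 0.279 for each). With limma, 0 of 20865 probes passed, against 3578 (17.1%) with an unadjusted p under 0.05, of which 1877 were higher and 1701 lower in null. The sign was the same in replicates 2 and 3, which share a slide, for 83.9% of probes, and in all 3 replicates for 40.4%; replicate 1 thus had the sign of the other replicates for 48.1% of the probes on which these had the same sign, no more often than an unrelated replicate would. Across probes, which are not independent replicates, the ratios of replicates 2 and 3 correlated at 0.93, those of replicates 1 and 2 at 0.06 and those of replicates 1 and 3 at −0.15. Leaving out replicate 1 gave 6425 probes higher and 5274 lower, and leaving out replicate 2 or 3 gave 0. Slide as a fixed block gave 4148 and 4385, but the same contrast on 1 value per slide gave 0 and 0, with 522 probes at an unadjusted p under 0.05. All 8 arrays with the replicate as a random effect gave 483 and 485 probes. By representative probe 613 genes were called, with 15 of the 23 named genes among them. The named genes were picked from these same arrays, so this overlap is no separate support.

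**Figure D2:**
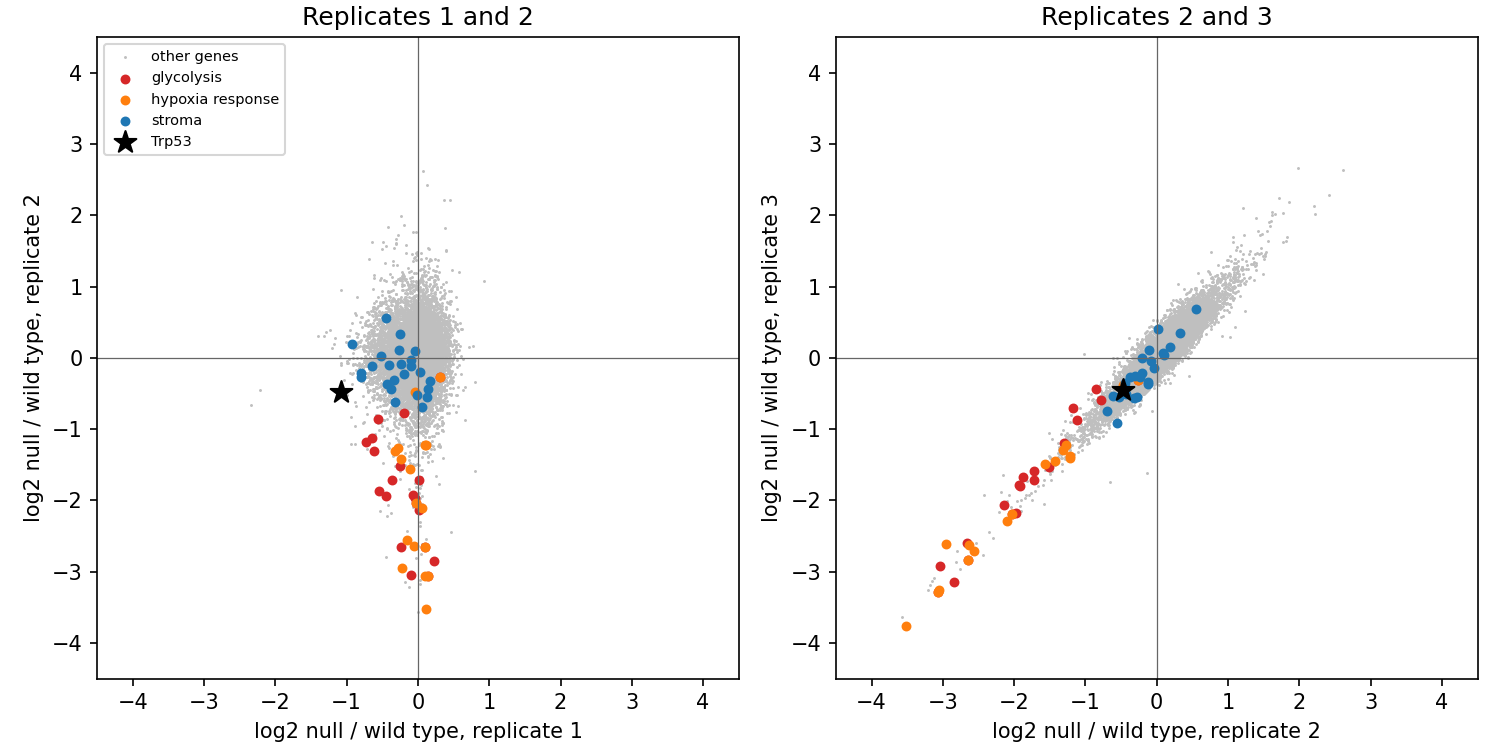
Log2 null over wild-type ratios of 12000 genes in replicate 1 against replicate 2 (left) and replicate 2 against replicate 3 (right); each point is a gene, with glycolysis, hypoxia and stroma genes coloured and Trp53 as a star. Replicates 2 and 3 follow one diagonal (r = 0.93 across probes) and replicates 1 and 2 do not (r = 0.06).

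Among 40 measured p53 target genes, 25 were lower and 15 higher in null, 15 of them lower in all 3 replicates. Cdkn1a, the cell cycle inhibitor, had −0.89 ± 0.53, with −0.27 in replicate 1 and −1.20 on slide 2. Ddit4 had −2.15 ± 1.71, with −0.18 in replicate 1 and −3.14 on slide 2. Ccng1 had −0.61 ± 0.26, the lipid transfer protein gene Pltp −0.59 ± 0.22, the DNA repair gene Xpc −0.35 ± 0.10 and Cd82 −0.46 ± 0.23. Mdm2, Bax and Zmat3 stayed near 0 (0.00, −0.06 and 0.06), and Trp53inp1 and Perp had 0.54 and 0.56. These 5, Cdkn1a and Ddit4 were chosen after their values were seen. The list p53 target genes was lower than other genes (median −0.09, camera adjusted p = 0.029), with adjusted p = 0.644 with an estimated correlation. With limma 0 genes passed over all probes and 0 adjusted over the list alone, while 11 had an unadjusted p under 0.05. The median was −0.10 in replicate 1 and −0.17 on slide 2, and without replicate 3 the list no longer passed (adjusted p = 0.0512). These medians hide members such as Cdkn1a and Ddit4 that were far lower on slide 2, while Xpc had −0.40 in replicate 1 and −0.32 on slide 2.

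Glycolytic genes were lower in null on all 20 measured members (median −1.31, 0.402 of wild type), and 9 passed when adjusted over the list alone, against 0 over all probes. Pkm, Gapdh, Eno1 and Hk1 had −0.88, −0.87, −1.04 and −0.62, each lower in all 3 replicates. Of the hypoxia response genes, which HIF transcription factors induce, all 17 measured members were lower (median −1.42), with 0 past the threshold over all probes and 0 adjusted over the list alone, and 12 with an unadjusted p under 0.05 (limma). Egln3 had −0.98 ± 0.56, the angiogenic factor gene Vegfa −0.93 ± 0.56, Egln1 −1.04 ± 0.69 and Ndrg1 −1.93 ± 1.49. Camera gave an adjusted p of 5.6e-10 for glycolysis and 5.2e-07 for hypoxia, with adjusted p = 0.644 and 0.666 with an estimated correlation. The lists share 4 genes. The glycolysis median was −0.15 in replicate 1, −1.90 in replicate 2 and −1.75 in replicate 3, and the hypoxia median was −0.03, −2.03 and −2.19.

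The heat shock genes Hspa1a and Hspa1b had −1.98 ± 1.33 and −1.48 ± 0.97, and Junb and Zfp36, which respond early to stimuli, had −1.07 ± 0.77 and −0.66 ± 0.42. The list immediate early and heat shock did not pass (18 measured, median −0.15, camera adjusted p = 0.131), with 0 members past either threshold and 8 with an unadjusted p under 0.05. It passed in 7 of 24 alternatives, among them without replicate 1 (adjusted p = 0.0217) and without replicate 2 (0.0187). Its median was −0.07 in replicate 1 and −0.28 on slide 2. Oxidative phosphorylation (22 measured, median 0.09, adjusted p = 0.160) and fatty acid oxidation (18 measured, median 0.00, adjusted p = 0.824) did not pass; their medians were 0.02 and −0.11 in replicate 1, and both 0.09 on slide 2. The electron carrier gene Cycs had 0.96 ± 0.69 and Sdhb, Cox5b and Ndufb5 had 0.39, 0.21 and 0.20, while Hadh, Etfb and Ppargc1a had −0.23, 0.25 and −0.41.

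**Figure D3:**
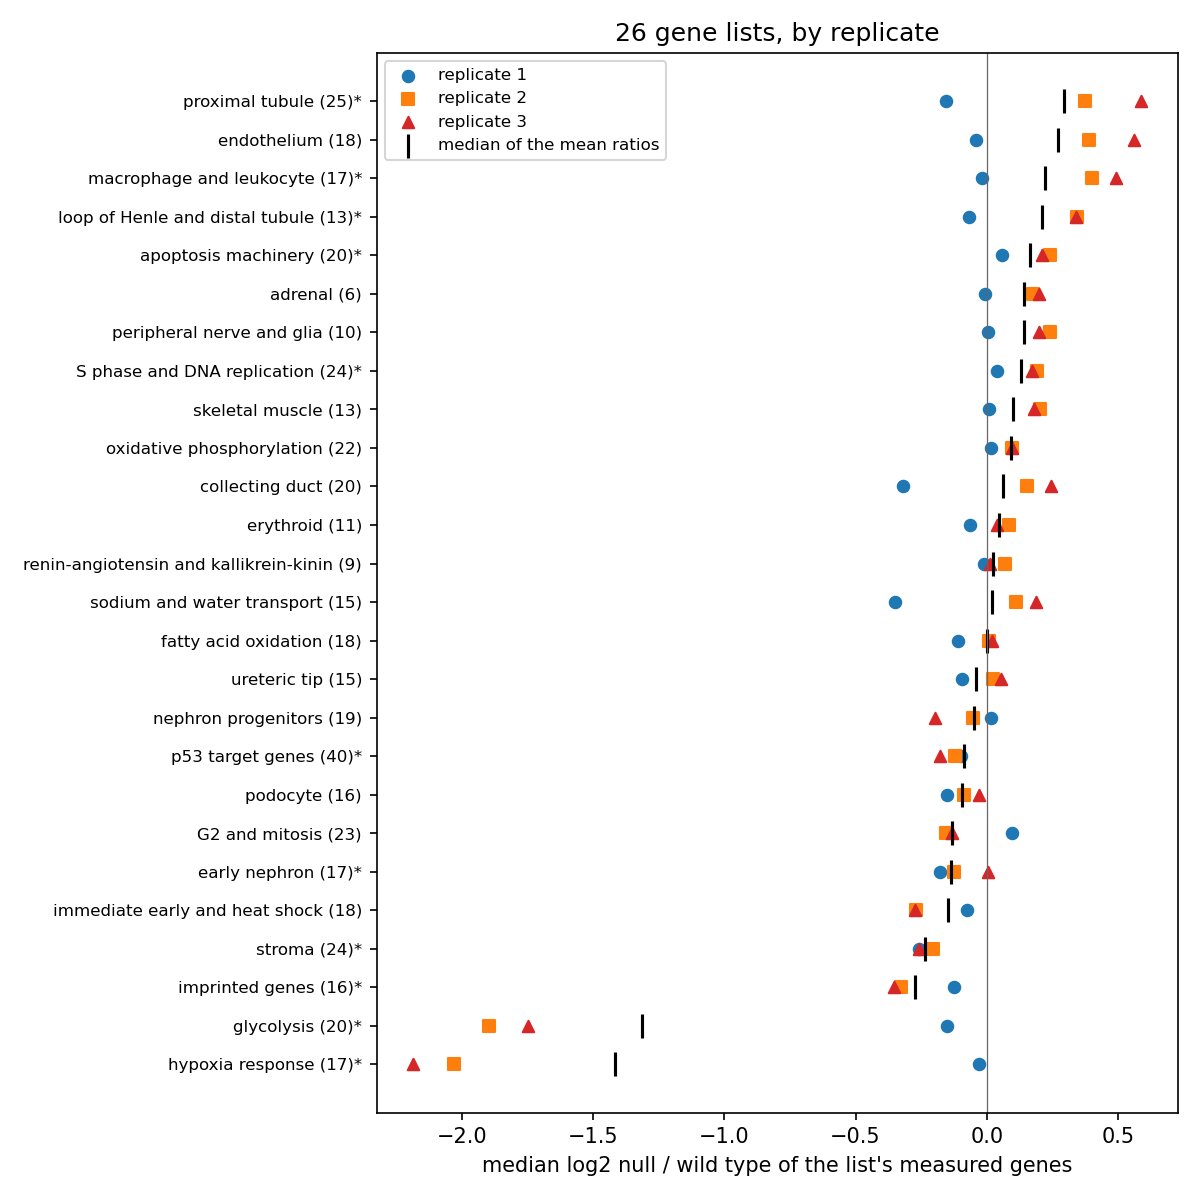
Median log2 null over wild-type ratio (x axis) of the measured genes of 26 lists (number of genes in brackets) in each replicate; the vertical tick is the median of the mean ratios, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Glycolysis sits at −0.15 in replicate 1 and at −1.90 and −1.75 in replicates 2 and 3, while stroma sits at −0.26, −0.21 and −0.26.

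The median of the stromal genes was lower in null by about the same amount in each replicate (−0.26, −0.21 and −0.26 in replicates 1, 2 and 3). The mean ratio was lower on 21 of 24 measured members, but only 11 were lower in all 3 replicates, so the medians and not all genes were alike. The matrix genes Fbln2, Col1a1 and Col3a1 had −0.39 ± 0.04, −0.49 ± 0.15 and −0.30 ± 0.04. The list was lower by camera (adjusted p = 0.00020), with adjusted p = 0.644 with an estimated correlation; 0 genes passed over all probes and 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05. Early nephron genes were lower on 13 of 17 members (median −0.14, camera adjusted p = 0.036, adjusted p = 0.644 with an estimated correlation). The cadherin gene Cdh6 passed adjusted over the list alone (−0.60 ± 0.16), and the Notch ligand gene Jag1 and the inducer gene Wnt4 had −0.37 and −0.31. The early nephron medians were −0.18 in replicate 1 and −0.09 on slide 2, and the list did not pass without replicate 1 (adjusted p = 0.179).

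Nephron progenitor genes did not pass as a list (19 measured, median −0.05, adjusted p = 0.224), with medians of 0.02 in replicate 1 and −0.06 on slide 2; Osr1, Uncx, Rspo1 and Dpf3 had −0.45, −0.39, 0.26 and −0.41. Markers of later tubules had higher medians. Proximal tubule genes were higher on 21 of 25 members (median 0.29, camera adjusted p = 0.0063, adjusted p = 0.685 with an estimated correlation), with medians of −0.15 in replicate 1 and 0.52 on slide 2. Slc2a2, Slc7a9 and Slc5a2 had 0.25, 0.72 and 0.36. Loop of Henle and distal tubule genes were higher on 11 of 13 members (median 0.21, camera adjusted p = 0.032, adjusted p = 0.685 with an estimated correlation), with −0.07 in replicate 1 and 0.34 on slide 2. Cldn16, Umod, Tmem52b and Sim2 had 0.41, 0.48, 0.17 and 0.33. In wild type Cldn16 and Umod were well above background on 6 and 7 of 8 arrays. Neither list had members past either threshold, and each had 1 with an unadjusted p under 0.05. Without replicate 3 the list proximal tubule (adjusted p = 0.0512) and the list loop of Henle and distal tubule (0.0738) did not pass.

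The epithelial sodium channel gene Scnn1g and the water channel gene Aqp3 passed adjusted over the sodium and water transport list alone (adjusted p = 0.0446 for each), at −0.82 ± 0.32 and −0.40 ± 0.09, but not over the collecting duct list, which holds them too (adjusted p = 0.0595 for each). That list did not pass as a whole (15 measured, adjusted p = 0.636), and its median of 0.02 lay above 0 while the test pointed down, with −0.35 in replicate 1 and 0.13 on slide 2; Sgk1 and Slc12a2 had 0.47 and −0.47. Collecting duct genes did not pass (20 measured, adjusted p = 0.638); the median was 0.06, with a mean of −0.02 and a test that pointed down (−0.32 in replicate 1, 0.23 on slide 2), and Krt19 and Krt18 had −0.44 and −0.27. Ureteric tip (15 measured, median −0.04, adjusted p = 0.752), podocyte (16 measured, median −0.09, adjusted p = 0.191), endothelium (18 measured, median 0.27, adjusted p = 0.115) and renin-angiotensin and kallikrein-kinin genes (9 measured, median 0.02, adjusted p = 0.808) did not pass and held 0 genes past either threshold. Their medians were −0.09, −0.15, −0.04 and −0.01 in replicate 1, and 0.01, −0.04, 0.48 and 0.03 on slide 2. Gfra1, Sox8 and Hoxb7 had −0.30, 0.25 and 0.20, with Sox8 well above background in wild type on 4 of 8 arrays; Clic5, Plce1 and Cd2ap had 0.33, −0.16 and −0.10. Cd34, Kdr, Tek and Gpihbp1 had 0.56, −0.30, 0.44 and −0.45; Agtr2, Ace and Agt had 0.21, 0.08 and 0.08, with Agt well above background in wild type on 6 of 8 arrays.

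S phase and DNA replication genes were higher in null on 18 of 24 members (median 0.13, camera adjusted p = 0.0095, adjusted p = 0.666 with an estimated correlation). The cyclin E genes Ccne2 and Ccne1 had 0.79 ± 0.40 and 0.94 ± 0.72, the thymidylate synthase gene Tyms 0.31 ± 0.15 and the clamp gene Pcna 0.42 ± 0.30, each higher in all 3 replicates. G2 and mitosis genes did not pass (23 measured, median −0.13, adjusted p = 0.101), with medians of 0.10 in replicate 1 and −0.17 on slide 2; Top2a, Tpx2, Kif23 and Bub1b had −0.34, −0.19, −0.19 and −0.27. Genes of the list apoptosis machinery were higher on 16 of 20 members (median 0.16, camera adjusted p = 0.029, adjusted p = 0.644 with an estimated correlation). The call was lost with median centring (adjusted p = 0.0984), a strict filter (0.0509) and lists without shared genes (0.0543). The pro-apoptotic gene Bcl2l11 and the anti-apoptotic gene Mcl1 had 0.81 ± 0.61 and 0.45 ± 0.35. All 3 lists held 0 genes past either threshold, with 5, 2 and 4 at an unadjusted p under 0.05. The S phase and apoptosis medians were 0.04 and 0.06 in replicate 1 and 0.24 and 0.23 on slide 2.

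Imprinted genes were lower on 14 of 16 members (median −0.27, camera adjusted p = 0.0012, adjusted p = 0.644 with an estimated correlation). Dlk1 passed adjusted over the list alone, and the growth factor gene Igf2, Grb10 and Peg3 had −0.40 ± 0.21, −0.41 ± 0.30 and −0.32 ± 0.22. The medians were −0.12 in replicate 1 and −0.37 on slide 2. Macrophage and leukocyte genes were higher on 15 of 17 members (median 0.22, camera adjusted p = 0.0023, adjusted p = 0.685 with an estimated correlation), with −0.02 in replicate 1 and 0.47 on slide 2. Aif1 and Adgre1, markers of macrophages, passed adjusted over the list alone (0.45 ± 0.09 and 0.51 ± 0.17), and Ptprc and Tyrobp had 0.43 ± 0.17 and 0.75 ± 0.45.

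Lists of other tissues a dissection may bring did not pass: erythroid (11 measured, median 0.05 with a mean of −0.12 and a test that pointed down, adjusted p = 0.845), adrenal (6, median 0.14, 0.521), skeletal muscle (13, median 0.10, 0.112) and peripheral nerve and glia (10, median 0.14, 0.115), the last number of each being its adjusted p. Their medians were −0.06, 0.00, 0.01 and 0.01 in replicate 1, and 0.10, 0.18, 0.18 and 0.21 on slide 2. Mc2r, Pnmt, Akr1b7 and Chgb had 0.33, 0.41, 1.03 and −0.89; Tnni2, Tnnc2, Tnnt3 and Mylpf had 0.35, 0.29, 0.28 and 0.25; Fabp7, Nefm and S100b had 0.23, 0.27 and 0.54. Gonad and liver lists had 4 measured genes each and were not tested. Cyp26b1, Dhh, Inha and Inhbb had −1.28, 0.80, −0.20 and 0.02, and Fgb, Afp, Ahsg and Trf had 0.63, 1.03, 0.42 and 0.04. The gonad median was −0.04 in replicate 1 and −0.12 on slide 2. All 4 liver genes were higher in null, with a median of −0.03 in replicate 1 and 0.78 on slide 2. Whether liver tissue came with the dissected kidneys was not tested. Inhbb and Ahsg were well above background on 6 of 8 arrays in null and on 4 of 8 in wild type.

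Genes of the sex chromosomes differed between replicates. Xist, the transcript of the inactive X chromosome, was well above background in wild-type RNA on all 8 arrays, and in null RNA on both arrays of replicate 2 and on no other array. It was at least 4.46-fold lower in null in replicate 1 and at least 3.14-fold lower in replicate 3, and had a log2 ratio of −0.66 in replicate 2. The Y-linked genes were not tested, since none was well above background in replicate 2. In null RNA Eif2s3y, Ddx3y and Kdm5d were well above background on all arrays of replicates 1 and 3. Eif2s3y and Kdm5d, not well above background on any array in wild-type RNA, were at least 6.78-fold and 2.90-fold higher in null in replicate 1 and at least 1.69-fold and 2.01-fold higher in replicate 3. Ddx3y was at least 3.44-fold higher in replicate 3; in replicate 1 it had a log2 ratio of 2.68, with wild-type RNA well above background on 2 of 4 arrays. Sry, Usp9y, Uty and Zfy1 were not well above background on any array in either genotype.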

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

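All tests for arrays that stand apart were run after the comparison, on 158 measures over the 8 arrays. The limit used flags about 1 in 20 measures by chance if arrays are independent. These arrays are repeats of 3 replicates on 2 slides, and the measures overlap, so that share does not apply here. Only 2 measures had 1 array far from the other arrays, which does not show that the arrays are sound. The median of the ureteric tip genes was −0.31 on 1 array of replicate 1 (null in Cy5, pair 2), against −0.08 to 0.04 on the others. Rragd had −0.55 on another array of replicate 1 (null in Cy5, pair 1), against −0.98 to −0.80 on the others, so it was lower in null on all 8 arrays.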

How the results depend on the processing

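The wild-type RNA of replicates 2 and 3 counted as 1 sample, and lists without shared genes, were chosen after seeing the data. Probes past the threshold, 0 higher and 0 lower, became 483 and 485 with all 8 arrays and the replicate as a random effect, 596 and 524 with a dye term added, and 4148 and 4385 with slide as a fixed block. Leaving out replicates gave 0 to 6425 higher and 0 to 5274 lower, the upper values without replicate 1. The fits with a random effect take 1 correlation for all replicates (0.546, and 0.721 with the dye term), and the residual of the slide block and of the fit without replicate 1 comes only from replicates 2 and 3, which share a slide. An unadjusted p with a 1.5-fold change gave 270 and 333. All other alternatives gave 0, among them 1 value per slide, which keeps none of the calls of the slide block, the fit with no replicate block (3 unpaired samples against 3) and the shared wild type as 1 sample (159 probes with an unadjusted p under 0.05). The brighter Trp53 probe stayed negative in all settings, at −0.77 with slide as a fixed block, where it passed, and at −0.78 to −0.46 without 1 replicate.

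The 11 lists past the threshold became 0 with an estimated correlation and 0 by fry, 8 to 13 without 1 replicate, and 8 to 12 in the other alternatives. The 0 with an estimated correlation also reflects the few degrees of freedom of that test, and not correlation between genes alone. Of 24 alternatives, the call held in 16 each for early nephron and the loop of Henle, 19 each for p53 targets and apoptosis machinery, 21 for proximal tubule and 22 for each of the other 6 lists. Of the list values, 569 stayed on the same side of the threshold, called or not called, while 14 gained a call and 41 lost one. The direction of the test never reversed where the list was called in the main setting or in the alternative. The median of a list called in the main setting could still change sign. It ran from −0.173 to 0.0043 for p53 targets and from −0.258 to 0.036 for early nephron. The immediate early and heat shock list gained a call in 7 alternatives, endothelium, G2 and mitosis, and peripheral nerve and glia in 2 each, and oxidative phosphorylation in 1. Glycolysis and hypoxia medians ran from −1.39 to −1.08 and from −1.57 to −1.21 over 6 background and normalization alternatives. Median centring moved the median of all tested probes to 0.12, against 0.01, and turned the gene Cd2ap to 0.176, the gene Hadh to 0.00891, the gene Inhbb to −0.0243, the gene Kif23 to 0.0137, the gene Krt18 to 0.0265 and the gene Tpx2 to 0.0550. The gene Inhbb also turned to −0.0423 and the gene Agtr2 to −0.012 with the shared wild type as 1 sample, and the gene Inhbb ran from −0.00905 to 0.0485 without 1 replicate, negative without replicate 1. The cause was not tested. On slide 2 the median spot lay 1.23 to 1.36 times over background in red, against 1.66 to 1.74 on slide 1, and fewer probes were well above background, which limits the genes that can be tested.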

Other observations

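The tests of explanations in this part were chosen after the values were seen, and the limits they were judged by were set with those values in view, so a pattern found and tested on the same data is weakly tested. Set before the data were examined were the hypothesis of an interval around Trp53, limma's test of each probe and the camera test of the erythroid list. The globin genes were singled out by reading through the members of the lists. The embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 had a mean ratio of −1.98 in replicate 2 and −2.23 in replicate 3, while Hba-a1, which encodes adult alpha globin, and the erythroid genes Alas2 and Slc4a1 had 1.38 and 1.71. The means of replicate 1 went the other way, with 0.24 and −0.43, although Hba-x itself was lower in null there too (−0.53). The erythroid genes Klf1, Rhd, Tspan33 and Epor lay between −0.24 and 0.25 in replicates 2 and 3, and the erythroid list did not pass (camera adjusted p = 0.845). None of these genes passed the threshold (smallest limma adjusted p = 0.279), and globin copies that are nearly identical are not told apart here.

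More blood of 1 kind in the null kidneys would raise these genes together, whereas the embryonic mean was −2.11 over replicates 2 and 3. The genes were picked for this split, so the values do not test that explanation. Other changes in the amount or kind of blood were not tested. A candidate explanation is that null kidneys of replicates 2 and 3 were at a later stage than the wild-type kidneys they were compared with: the means of Hba-a1, Alas2 and Slc4a1 and of the embryonic globin genes differed by 3.65, and the proximal tubule medians were 0.38 and 0.59. It rests on 6 genes picked for the pattern, and the labels give 1 age for all kidneys, so staging stays a hypothesis, and genotype or litter could also account for the values. These replicates lie on 1 slide.

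Glycolysis and hypoxia genes were far lower in null in replicates 2 and 3 than in replicate 1. From slide 1 to slide 2 the wild-type level of the glycolysis genes was higher by a median of 1.501 and the null level by 0.22 (all genes, 0.13 and 0.25), and hypoxia genes by 2.28 and 0.20. The wild-type values lay at percentile 100 of 10000 random lists matched on intensity. Random genes were drawn independently, while these lists had estimated correlations of 0.86 and 0.99 and were singled out for their shift. The percentile is therefore no measure of chance. By the levels alone, the difference may come from the wild-type RNA of replicates 2 and 3, and how those kidneys were handled is not given in the sources used here. Whether both replicates used 1 wild-type RNA cannot be told apart from similar samples: the wild-type levels of replicates 2 and 3 differed with an SD 0.93 times and a MAD 1.15 times those of repeat arrays of replicate 1. The null levels of replicates 2 and 3 lay further apart, with an SD of 0.169 and a MAD of 0.146 (log2), against 0.108 and 0.096 for the wild type. An effect of the genotype also stays open, since only replicate 1, with a median of −0.15, lies on the other slide.

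Y-linked genes were higher and Xist lower in null in replicates 1 and 3. The 3 Y-linked genes well above background in their null RNA, Eif2s3y, Ddx3y and Kdm5d, were higher on 6 of 6 arrays of these replicates. They were taken because they were well above background in null RNA, so this count could hardly differ and does not test noise of dim spots. In these replicates, where 1 genotype was below background, the Y-linked genes were higher in null, and Xist lower, by a lower bound above 0, the smallest bound being a log2 difference of 0.757 (Eif2s3y, replicate 3). A bound is given only where 1 genotype was well above background and the other was not, so a value above 0 was nearly fixed in advance. Which genotype was the brighter one was not fixed by that rule. In replicate 2 the Y-linked genes were below background in both genotypes and gave no bound. A larger share of male kidneys in the null RNA of replicates 1 and 3 could account for these values, so sex may add to genotype in these ratios. For any gene, effects of sex and of genotype cannot be told apart within these replicates. Xist was lower in replicate 2 too (−0.66), and X-linked partners of Y-linked genes did not all follow the split. Kdm6a did, with −0.54, −0.24 and −0.66 in replicates 1, 2 and 3. The Kdm5c probes had −0.28 and −0.06 in replicate 1, but −0.56 and −0.73 in replicate 2. The Eif2s3x probes had −0.55, 0.96 and −0.17 in replicate 1. X-linked genes were 2.83% of the 1094 higher and 2.29% of the 1047 lower genes with 1 sign and an unadjusted p under 0.05, against 3.22% of all genes; of the 12 named genes with higher values in null, 3 are X-linked (Xlr3c, Wdr13 and Rgn).

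Of 19 measured genes of the retinoic acid pathway, a list chosen after Dhrs3 and Rarb were seen and sharing 4 genes with the lists above, 16 were lower in null, 9 of them in all 3 replicates. Dhrs3 had −1.03, Tgm2 −0.72, Nrip1 −0.54 and Cyp26b1 −1.28, while Aldh1a1 had 0.40; 0 passed the threshold over all probes. The list median was −0.21 (−0.05, −0.19 and −0.20 by replicate), with a camera p of 0.0018 and p = 0.138 with an estimated correlation (adjusted p = 0.0035 and 0.247 over the 2 lists chosen this way), so a lower pathway as a whole may be there but was not shown. The other list, 13 measured circadian clock genes chosen after Per1 was seen, did not pass: 7 were lower, the median was −0.16 (−0.12, −0.23 and −0.07 by replicate), 7 had an unadjusted p under 0.05 and 0 passed over all probes, and camera gave p = 0.126, and p = 0.247 with an estimated correlation. Bhlhe40 had −2.20, Dbp −1.05, Per1 −0.81, Tef −0.56 and Nfil3 −0.50, while Arntl had 0.52 and Clock 0.36. In replicate 1 alone these genes had, in the same order, −0.13, −0.12, −0.89, −0.20, −0.24, 0.00 and 0.22. Except for Per1, their means thus came mostly from replicates 2 and 3.

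A knockout made in cells of another strain may carry that strain's alleles near the gene. Within 10 Mb of Trp53 on chromosome 11, 0 genes passed the threshold, and 44 of 264 (16.7%) had an unadjusted p under 0.05, against 2132 of 11735 elsewhere (18.2%). The odds ratio was 0.90 (95% interval 0.63 to 1.25, Fisher's exact test, two-sided p = 0.572), and 0.80 against 756 other genes of the chromosome (p = 0.275). The count by unadjusted p was chosen after 0 genes had passed, and an excess is neither shown nor excluded.

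With 3 replicates, 4 assignments of signs exist, too few for a share under 0.05. The real one gave 3578 probes with an unadjusted p under 0.05, and the highest other, with replicate 1 turned, gave 4602, so 2 of 4 gave as many as the real one. For lists past the threshold the real one gave 11 and the highest other 9, again with replicate 1 turned, so 1 of 4 reached 11. As replicate 1 sits alone on slide 1, turning it follows the slides; the within-slide and blocked counts are given with the alternatives.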
